A study of Mus musculus with 4 samples.

How the data were processed

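MicroRNA levels were measured on 4 one-colour microarrays, 1 for each combination of tumour site (primary tumour or metastases) and treatment (sham or 10 Gy). Per the labels' protocols, total RNA (2 µg) was tailed with poly(A), joined to an oligonucleotide tag for Cy3 staining and hybridised by a service provider on microfluidic chips. The array's replicate number is 1 in every group, so no group has a second array. Each chip carried 3968 spots, of which 3500 belonged to 700 mouse microRNA probes with 5 spots each, 180 were empty and 20 belonged to 5 probes for 5S ribosomal RNA.

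The deposited scanner tables hold the mean intensity of each spot on a linear scale, per the file headers, together with the deposited standard deviation of intensity inside the spot, which was not used further. The empty spots of these tables lie far above 0, so the background had not been subtracted. Large intensities were written with a comma between groups of digits, which was removed before use, and all values were checked to be numbers above 0. The authors' value table holds a background-subtracted intensity per probe, as found by setting it against the scanner tables: the correlation with the mean of a probe's spots was at least 0.99996 on each array, and the median difference from the scanner mean was 160.7, 176.4, 379.9 and 221.9 intensity units on the primary sham, metastases sham, primary 10 Gy and metastases 10 Gy arrays. It lists 346, 354, 310 and 590 probes in the same order, with column medians of 178.9, 212.6, 129.6 and 55.88 intensity units, and no scaling between arrays was visible. How the background was chosen for it, the scanner software and its version are not given in the sources used here. The value table was used only as an alternative.

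Background was corrected with normexp and an offset of 50 over all spots of each array (limma 3.58.1 in R 4.3.3). The offset shrinks differences from dim probes. Values were taken to log2, the 5 spots of a probe were averaged, and the 4 arrays were quantile normalized over the microRNA probes. A probe counted as detected on an array when at least 3 of its 5 spots exceeded the 95th percentile of that array's empty spots. The error printed after ± is the SD over the 5 pairs of spots at the same position in a probe's set on the 2 arrays compared. It covers only the scatter of spots within the 2 chips. Error between chips, such as that of labelling, hybridisation or scaling, and the spread between animals are not part of it.

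Each of the 4 pairwise comparisons (10 Gy against sham at each site, and metastases against primary tumour in each arm) is a log2 difference of 2 arrays without a test. Probes detected on at least 1 of the 2 arrays were counted where they differed by at least 1 on the log2 scale, which is 2-fold. A probe detected on 1 of the 2 arrays has only a bound, computed as the brighter value minus the higher of the dim probe's own value and the lowest value among probes detected on the dim array, and is written as "at least N-fold". The difference between the 2 radiation responses was taken per probe over the 374 probes detected on at least 2 arrays. An additive limma fit with site and radiation as terms, on those probes, leaves 1 residual degree of freedom (prior degrees of freedom 1.519). Its p, with Benjamini-Hochberg adjustment at 0.05, tells only whether a site or radiation difference is large against the disagreement between the 2 arms or sites. It takes in no spread between animals. The radiation term pools the treated primary tumour with metastases of treated mice.

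Before the data were examined, 21 lists of microRNAs were fixed: miR-21, the miR-200 family, other epithelial microRNAs, p53 targets, the let-7 family, the miR-17-92 cluster and its paralogs, metastasis-promoting and metastasis-suppressing microRNAs, inflammation and NF-kB, hypoxia, myeloid cells, lymphocytes, erythroid cells, endothelium, fibroblasts and smooth muscle, skeletal and heart muscle, hepatocytes, lung, neural microRNAs, the Sfmbt2 cluster, and probes prone to pick up fragments of other RNAs or GC-rich RNA. Of their members, 147 were matched to a probe by mature name and arm and 19 were not. For lists with at least 3 detected members, the median log2 difference was placed among 10000 random lists of the same size matched on mean signal in 10 bins. The percentile describes these arrays and is no p-value. The microRNAs named were also fixed by a rule before the data were examined: per comparison, the 6 highest and 6 lowest differences among probes detected on both arrays whose spots do not overlap, the 3 largest bounds in each direction, miR-21 and its passenger strand, and up to 4 members of each list described, those with the highest mean signal. Names are those of the array, in an older form in which a star marks the passenger strand. Gene names and neighbouring genes come from a RefSeq gene table of assembly GRCm38.p6, in which 629 of the 700 probes matched a gene. No coordinates are given, because the deposited files name no genome build.

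The procedure was tested on simulated data made for the comparison of metastases with primary tumour without radiation, with 337 probes tested and an SD of 0.2 between arrays. Of 30 probes changed 2-fold, 13 were counted at 2-fold and 30 had the right sign, with a median estimate of 0.959 on the log2 scale. Of 30 changed 4-fold, 26 were counted and 29 had the right sign, with a median estimate of 1.75. None (0) of 277 unchanged probes was counted at 2-fold. The additive fit called 28 of the 30 probes changed 2-fold, 28 of the 30 changed 4-fold and 7 of the unchanged ones. All simulated arrays were built from the primary sham profile with the same noise for every probe. They held no radiation effect and no site difference that varied between arms. The changed probes were drawn only from those well above the empty spots. These counts therefore do not give the power of the procedure on the real arrays.

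Alternatives fixed before the data were examined covered the background correction (none, or offset 16), the scaling between arrays (cyclic loess, the 75th percentile of probes detected on all 4 arrays, or none), the median of spots, the filter on dim probes, leaving out the repeat-cluster and RNA fragment probes, the authors' value table, thresholds of 1.5-fold and 4-fold, and an additive fit without the other factor. Added after seeing the data were a stricter detection rule, at least 3 of 5 spots above 2 times the median of the empty spots, and counts and list medians with each probe detected on 1 of the 2 arrays at its bound, or at 0 where the bound shows no difference. Without that alternative, counts and list medians use the measured values of such probes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the comparisons and plots.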

Results

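The arrays measured microRNAs in tumours grown from 4T1 cells, a mouse mammary carcinoma line that forms metastases after injection into the mammary gland. Per the labels, 20 female mice received 50000 cells each, and when the tumour had reached 1 cm3 the primary tumour was treated with sham radiation in 10 mice and with 10 Gy in the other 10. The primary tumour was then removed by surgery and metastases were left to grow. The irradiated site was thus the primary tumour, and "metastases, 10 Gy" stands for metastases in mice whose primary tumour had been irradiated. The arrays of the 10 Gy groups are called irradiated arrays for short. There was 1 array for each of the 4 groups, so no difference below has a replicate check, and the precision is limited by the number of arrays. The labels do not say in which organ the metastases lay, or whether the RNA of an array came from 1 mouse or several.

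The arrays differed in background. The median intensity of the empty spots was 171.5 on the primary sham array, 177.2 on the metastases sham array, 416.9 on the primary 10 Gy array and 252.4 on the metastases 10 Gy array. The intensity of the empty spots had a correlation with chip row of 0.60, 0.17, -0.62 and -0.52 in the same order. No setting corrected for such a trend. Of 700 microRNA probes, 337, 459, 186 and 339 were detected on these arrays in the same order, 180 on all 4 and 492 on at least 1. Over all probes, the correlation of normalized levels across probes was 0.97 between the 2 metastases arrays and 0.92 between the 2 primary tumour arrays, and ranged from 0.88 to 0.92 between a primary tumour array and a metastases array. Probes are not independent replicates.

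miR-21, the microRNA in the series title and a well-known oncogenic microRNA, was among the brightest probes on every array. The probe targets UAGCUUAUCAGACUGAUGUUGA, and the gene, Mir21a, lies within the span of Vmp1. Its normalized log2 level was 14.60 in the primary tumour after sham treatment, 15.31 in metastases after sham treatment, 15.08 in the primary tumour after 10 Gy and 15.15 in metastases after 10 Gy. The irradiated primary tumour exceeded the sham primary tumour by 0.48 ± 0.04 on the log2 scale, and the metastases exceeded the primary tumour without radiation by 0.72 ± 0.04. The metastases of irradiated mice differed from those of sham mice by -0.17 ± 0.16 and from the irradiated primary tumour by 0.07 ± 0.10. All 4 differences were under 2-fold, and each changed sign under at least 1 other scaling: in this order, they became -0.088 without normalization, -0.12 with scaling to the 75th percentile, 0.084 with cyclic loess and -1.24 with scaling to the 75th percentile. The passenger strand miR-21* lay close to background, at 60.60 intensity units above the empty spots on the primary sham array and 33.05 on the metastases sham array, and was not detected on the 2 irradiated arrays.

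**Figure D1:**
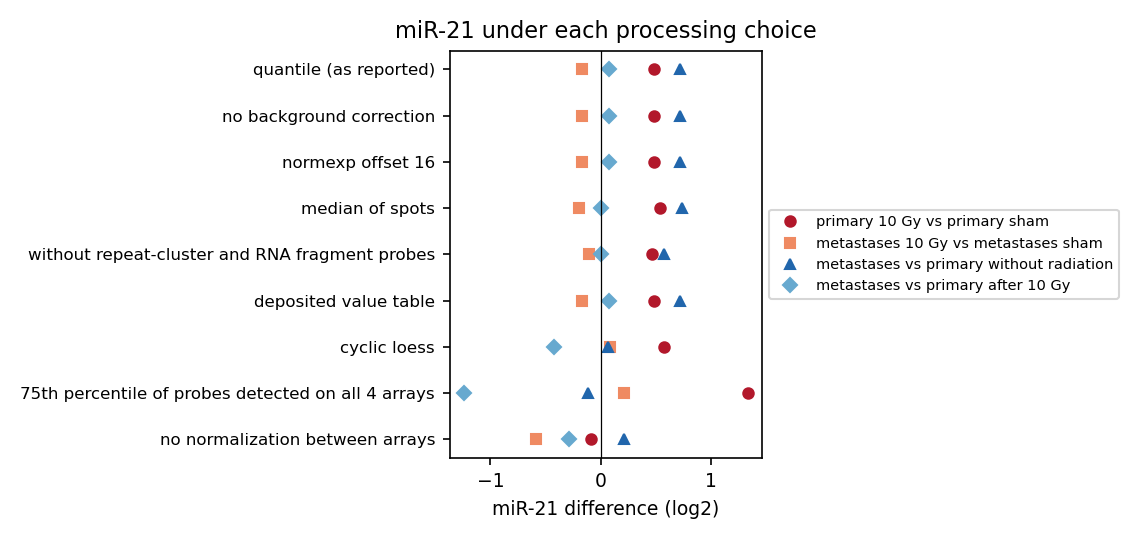
Log2 difference of miR-21 (x axis) in the 4 comparisons (symbols) under each processing choice (rows), with 1 array per group. The difference between irradiated and sham primary tumour runs from -0.088 without normalization to 1.33 with scaling to the 75th percentile, and each comparison has points on both sides of 0.

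The first question of the design is how the irradiated primary tumour differed from the sham-treated one. miR-1, miR-133a and miR-133b, microRNAs of skeletal and heart muscle, were the 3 with the largest positive difference: miR-1 was higher by 4.82 ± 0.34 on the log2 scale (28.3-fold), miR-133a by 3.21 ± 0.21 (9.28-fold) and miR-133b by 2.64 ± 0.34 (6.25-fold). Without normalization these 3 differences were 3.76, 2.12 and 1.63. The next were miR-764-5p (2.49 ± 0.24), whose gene lies within Htr2c, and the mesenchymal microRNAs miR-214 (2.28 ± 0.18) and miR-143 (2.12 ± 0.28), at 1.52, 1.12 and 1.05 without normalization. Of these, miR-133b, miR-764-5p and miR-143 were not above 2 times the empty spots on either array. The largest negative differences were those of miR-466h (-3.90 ± 0.15), miR-466f (-3.23 ± 0.08), miR-466f-5p (-3.18 ± 0.43), miR-466j (-2.95 ± 0.06), miR-468 (-3.16 ± 0.10) and miR-711 (-3.51 ± 0.12). miR-466 probes belong to a repeat-rich family, many of whose genes lie within Sfmbt2, and several of their targets hold UG repeats. miR-711 is on the list of RNA fragment and GC-rich probes. Among probes detected on only 1 of the 2 arrays, miR-669e was at least 8.07-fold lower after 10 Gy, miR-877* at least 5.55-fold and miR-1982* at least 4.34-fold, while miR-1191 was at least 3.31-fold higher and miR-429 at least 1.80-fold.

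In all, 51 of 339 probes were at least 2-fold higher and 52 at least 2-fold lower in the irradiated primary tumour. The split depended on the scaling: it was 28 higher and 62 lower with cyclic loess, 190 and 25 with scaling to the 75th percentile, which shifted the median of all probes to 1.13, and 7 and 95 without normalization, with a median of -0.29. Of the muscle list, 3 of 4 detected members were at least 2-fold higher and none (0) lower, with a median difference of 2.93 ± 0.25, above all random lists. miR-206, the brightest member, differed by -0.98 ± 0.16. The targets of miR-133a and miR-133b differ only in the last base, and those of miR-1 and miR-206 share most of their sequence. Probes with such similar targets need not give separate signals, which the random lists do not allow for, and cross-hybridisation was not tested. The list of fibroblast and smooth muscle microRNAs had 5 of 10 detected members at least 2-fold higher, with a median of 0.96 ± 0.15 (percentile 99.8 of random lists). Its brightest members were miR-29a (0.77 ± 0.04, but negative without normalization), miR-214, miR-145 (1.78 ± 0.20) and miR-143. Of the miR-17-92 cluster and its paralogs, which promote proliferation, 6 of 10 were at least 2-fold higher, among them miR-17 (1.80 ± 0.18) and miR-20a (1.41 ± 0.07), with miR-92a at 0.77 ± 0.10 and miR-25 at 0.40 ± 0.08, both negative without normalization. The median of this list was 1.23 ± 0.17 (percentile 98.3). Of the p53 targets, 2 of 6 were at least 2-fold higher, miR-145 and miR-107 (1.25 ± 0.30), and miR-34a, a direct target of p53, differed by 0.94 ± 0.29. Both members past 2-fold are shared, miR-145 with the fibroblast and smooth muscle list and miR-107 with the metastasis-promoting list. The median of the p53 targets was 0.74 ± 0.26 (percentile 99.6), and a response of p53 was not tested. The medians of these 4 lists stayed above 0 under every scaling, but without normalization they were 1.87 for muscle, 0.17 for the p53 targets, 0.064 for miR-17-92 and 0.014 for fibroblasts and smooth muscle. Only 3 of the 6 p53 targets were detected on both arrays, and with the others at their bounds the median was 0.47. The list of the Sfmbt2 cluster had a median of -1.34 ± 0.21 (percentile 0.19), which was -0.080 with scaling to the 75th percentile. Of the list, miR-467a, miR-467b and miR-669a were matched to genes within Sfmbt2, miR-467f and miR-669n lie in other genes, and the rest matched no gene. miR-467a, miR-467b and miR-669a were not detected on either primary tumour array, so the median does not include them. Of the 8 detected members of the Sfmbt2 list 5 were detected on both arrays, and with the others at their bounds 3 were at least 2-fold lower and the median was -0.69 (percentile 2.02). miR-223, a microRNA of myeloid cells, was lower by a difference of -2.91 ± 0.26.

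The remaining lists had median differences that lay within the middle 95% of random lists. They were 0.87 ± 0.10 for metastasis-promoting microRNAs, 0.57 ± 0.17 for lymphocytes, 0.40 ± 0.13 for other epithelial microRNAs and 0.35 ± 0.07 for inflammation and NF-kB, all 4 of which were negative without normalization. They were 0.08 ± 0.16 for the let-7 family, 0.06 ± 0.11 for lung, 0.05 ± 0.20 for metastasis-suppressing microRNAs and -0.20 ± 0.09 for the RNA fragment and GC-rich probes, and each of these 4 changed sign under at least 1 other scaling. Too few members were detected for the median of the other lists. Among them, the erythroid miR-451 differed by -0.41 ± 0.09. The hypoxia-induced miR-210 differed by 0.87 ± 0.15, the endothelial miR-126-3p by 0.65 ± 0.11, the erythroid miR-486 by 0.42 ± 0.15 and the neural miR-128 by 0.36 ± 0.16, and these 4 were negative without normalization. The hepatocyte microRNA miR-192 was not detected in the irradiated primary tumour.

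**Figure D2:**
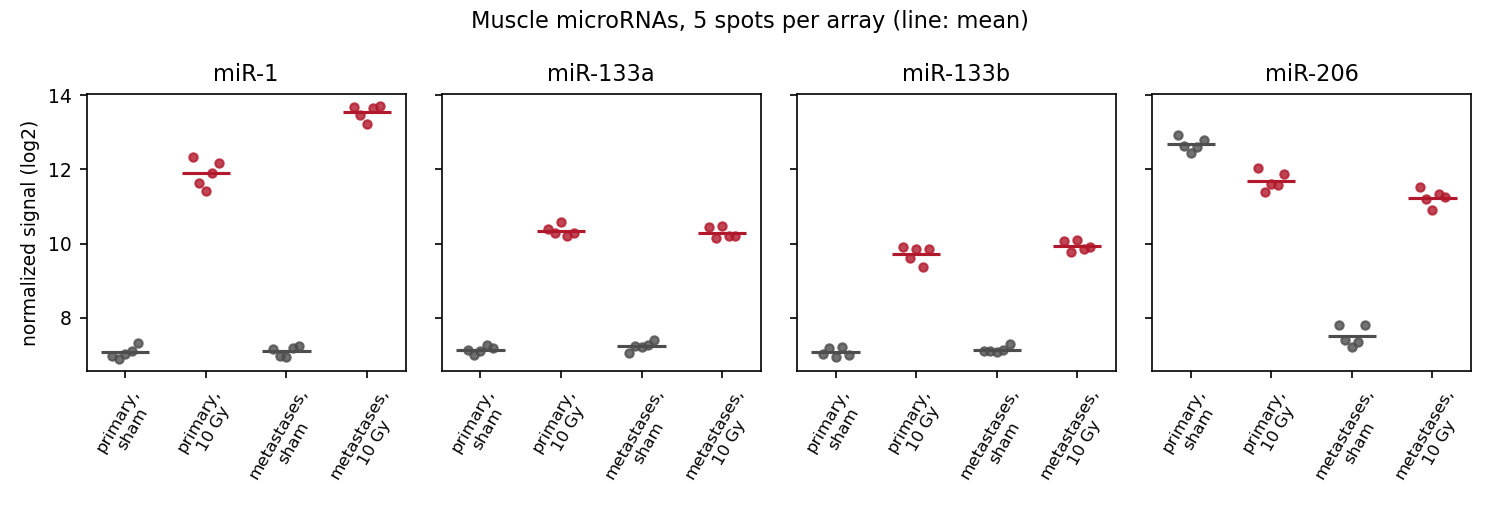
Normalized log2 signal (y axis) of 4 muscle microRNAs on the 4 arrays (x axis), with each of the 5 spots as a point and their mean as a line; grey marks sham and red 10 Gy. miR-1, miR-133a and miR-133b lie higher on both irradiated arrays (miR-1 at 11.89 and 13.54 against 7.07 and 7.10), whereas miR-206 is highest in the sham primary tumour, at 12.68.

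The second question is how metastases differed between mice whose primary tumour had been irradiated and sham-treated mice. Here too miR-1 (6.44 ± 0.09, 86.9-fold), miR-133a (3.05 ± 0.26) and miR-133b (2.79 ± 0.19) were higher, together with miR-206 (3.73 ± 0.19), which is made in skeletal muscle. miR-203, typical of stratified epithelium such as skin, was higher by 3.35 ± 0.30 (10.2-fold), and miR-122, the main microRNA of hepatocytes, by 2.64 ± 0.30 (6.21-fold). The largest negative differences were those of miR-874 (-2.26 ± 0.37), whose gene lies within Klhl3, miR-98 (-2.04 ± 0.38), a member of the let-7 family whose gene lies within Huwe1, miR-671-5p (-1.81 ± 0.22), miR-714 (-1.56 ± 0.30), miR-1956 (-1.49 ± 0.29) and the lymphocyte microRNA miR-150 (-1.19 ± 0.15). Of these, miR-714 is on the list of RNA fragment and GC-rich probes. Among probes detected on 1 array, miR-1898 was at least 3.06-fold lower, miR-450a-5p and miR-365 at least 1.47-fold lower, miR-124 at least 1.44-fold higher and miR-669k and miR-154 at least 1.2-fold higher.

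Only 11 of 481 probes were at least 2-fold higher and 12 at least 2-fold lower in metastases of irradiated mice. Scaling to the 75th percentile gave 44 and 10, with the median of all probes at 0.59, and no normalization gave 7 and 71, with the median at -0.20. All 4 detected muscle microRNAs were at least 2-fold higher, with a list median of 3.39 ± 0.17, above all random lists and positive under every scaling. As in the primary tumour, the similar targets of these probes need not give separate signals. No other list had a median outside the middle 95% of random lists. Of 5 miR-200 family members, which keep epithelial cells epithelial, none (0) differed by 2-fold and the median was -0.38 ± 0.22 (percentile 5.28); the miR-17-92 list had a median of -0.23 ± 0.16 (percentile 4.16). The medians were -0.42 ± 0.19 for lymphocytes, -0.27 ± 0.18 for inflammation and NF-kB, -0.17 ± 0.18 for metastasis-promoting and -0.15 ± 0.15 for metastasis-suppressing microRNAs, and -0.15 ± 0.17 for lung. Those of 5 lists turned positive with scaling to the 75th percentile: -0.23 ± 0.29 for myeloid cells, -0.053 ± 0.12 for erythroid cells, -0.048 ± 0.13 for fibroblasts and smooth muscle, -0.043 ± 0.29 for p53 targets and -0.015 ± 0.18 for the RNA fragment probes. Those of 4 lists turned negative without normalization: 0.022 ± 0.20 for the Sfmbt2 cluster, 0.026 ± 0.23 for hepatocytes, 0.052 ± 0.32 for neural microRNAs and 0.13 ± 0.26 for other epithelial microRNAs. The let-7 family was at 0 ± 0.14 and took either sign under the other scalings. Of the lists too small for a median, miR-210 differed by 0.51 ± 0.25 and miR-126-3p by 0.13 ± 0.15, both negative without normalization.

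The difference between the 2 radiation responses, metastases minus primary tumour, was at least 1 for 45 of 374 probes and at most -1 for 44. Scaling to the 75th percentile gave 28 and 127, cyclic loess 58 and 34, and no normalization 54 and 34. The response was at least 2-fold in opposite directions for 4 probes, against 1 without normalization, 6 with cyclic loess and 10 with scaling to the 75th percentile. The 4 were miR-466f (-3.23 in the primary tumour and 1.88 in metastases), miR-466j (-2.95 and 1.18), miR-574-5p (-1.19 and 1.37) and miR-1187 (-1.01 and 1.56). Across probes, the 2 responses had a Pearson correlation of 0.25 and a Spearman correlation of 0.20. Of the probes at least 2-fold higher, 3 were shared (1.5 expected for independent lists), miR-1, miR-133a and miR-133b, and of those at least 2-fold lower, 7 were shared (1.64 expected). The near-identical targets of miR-133a and miR-133b limit the first of these counts.

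**Figure D3:**
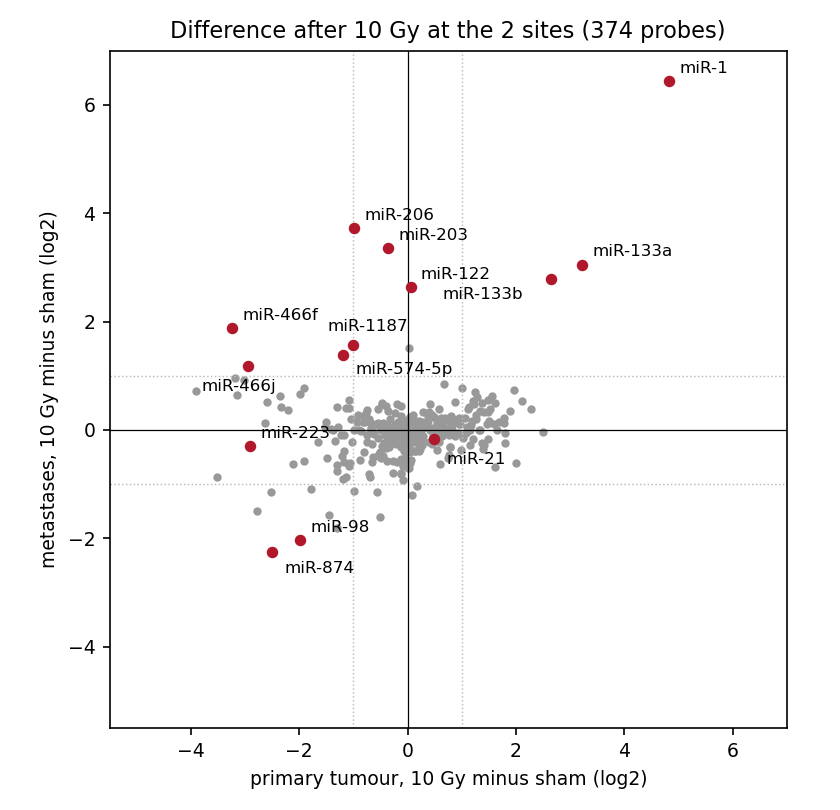
Difference between 10 Gy and sham in log2 units in the primary tumour (x axis) and in metastases (y axis) for the 374 probes detected on at least 2 arrays, 1 point per probe, with dotted lines at 2-fold and red points for labelled microRNAs. miR-1, miR-133a and miR-133b lie above 2-fold on both axes, while miR-466f, miR-466j, miR-574-5p and miR-1187 lie beyond 2-fold in opposite directions.

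The third question is how metastases differed from the primary tumour without radiation. miR-200c, an epithelial microRNA, was higher in metastases by 4.02 ± 0.12 (16.2-fold). The difference was 4.40 with the smaller normexp offset and 3.11 without background correction, since an offset or a background left in shrinks differences from dim probes. miR-200b, not detected in the primary tumour, was at least 13.6-fold higher, with miR-429 at least 3.44-fold and miR-200a at least 3.23-fold higher. miR-143 (3.92 ± 0.10) and miR-145 (12.1-fold), made in smooth muscle and fibroblasts, the lymphocyte microRNA miR-150 (3.76 ± 0.11), miR-29c (3.22 ± 0.26) and miR-30a (3.21 ± 0.23) were the other 5 with the largest positive difference. The muscle microRNA miR-206 had the largest negative difference, -5.17 ± 0.11 (35.9-fold lower), followed by miR-466j (-4.57 ± 0.11), miR-466h (-4.55 ± 0.24), miR-468 (-4.46 ± 0.25), miR-1898 (-4.43 ± 0.13) and miR-672 (-4.34 ± 0.09). Bounds in the lower direction were small, at least 1.91-fold for miR-294, 1.79-fold for miR-99b* and 1.43-fold for miR-200a*.

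Of 473 probes, 57 were at least 2-fold higher and 50 at least 2-fold lower in metastases; cyclic loess gave 53 and 74, and scaling to the 75th percentile, with the median of all probes at -0.24, gave 58 and 70, while no normalization gave 88 and 52. The lung list had 6 of 10 detected members at least 2-fold higher, counting probes detected on 1 array by their bounds, and none (0) lower. Its median was 1.94 ± 0.14, above all random lists. Its brightest members were miR-126-3p (2.52 ± 0.10), also endothelial, miR-30b (2.27 ± 0.17), miR-30c (1.97 ± 0.17) and miR-30d (1.92 ± 0.11). The others past 2-fold were miR-30a and miR-195, and the miR-30 members have similar targets. The dim miR-218, miR-34b-3p, miR-34c and miR-449a, detected only in metastases, were at least 1.97-, 1.6-, 1.23- and 1.085-fold higher. The miR-200 family had 4 of 5 members at least 2-fold higher and a median of 1.93 ± 0.32, above 99.96% of random lists. Only 1 member was detected on both arrays, and at the bounds the median was 1.78. Fibroblast and smooth muscle microRNAs had 7 of 11 at least 2-fold higher (median 1.54 ± 0.21, percentile 99.9). Metastasis-suppressing microRNAs, a list that shares miR-126-3p and miR-30 members with the lung list, had 7 of 11 higher and 1, miR-206, lower (median 1.44 ± 0.18, percentile 99.9). The p53 targets (2 of 9 higher, median 0.75 ± 0.21, percentile 99.7) and the miR-17-92 cluster (5 of 13 higher, median 0.75 ± 0.12, percentile 97.7) lay above the middle 95% as well. The Sfmbt2 cluster had 5 of 11 members at least 2-fold lower and a median of -0.89 ± 0.13 (percentile 0.045). Of its members matched to genes within Sfmbt2, miR-467a and miR-669a were detected only in metastases, at least 1.16- and 1.25-fold higher. miR-467b was not detected in the primary tumour either. The medians of all these lists kept their sign under every scaling.

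Of the remaining lists without radiation, the medians were 1.45 ± 0.08 for lymphocytes, 1.42 ± 0.04 for erythroid cells (miR-451 at 2.95 ± 0.10 and miR-486 at 1.42 ± 0.04), 0.71 ± 0.25 for hepatocytes and 0.60 ± 0.04 for inflammation and NF-kB. They were 0.53 ± 0.07 for the let-7 family, 0.37 ± 0.05 for metastasis-promoting microRNAs, 0.24 ± 0.22 for myeloid cells, 0.12 ± 0.11 for other epithelial microRNAs, 0.05 ± 0.04 for muscle and -0.16 ± 0.07 for the RNA fragment probes, all within the middle 95% of random lists. Those for myeloid cells, other epithelial microRNAs and muscle changed sign under at least 1 other scaling. miR-210 differed by -0.16 ± 0.14 and the neural miR-128 by 0.57 ± 0.17.

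The last question is how metastases differed from the primary tumour in the irradiated arm. miR-451 (3.26 ± 0.14), miR-30a (3.04 ± 0.13) and miR-15a (2.68 ± 0.15) were higher in metastases, as were miR-1937b (3.26 ± 0.22), miR-1937a (2.94 ± 0.24) and miR-711 (3.19 ± 0.14). This difference of miR-711 and its fall in the primary tumour after 10 Gy use the same irradiated primary tumour level, 9.14, and are not independent. miR-203 was at least 18.8-fold higher, miR-200c at least 15.5-fold and miR-200b at least 6.15-fold, since none of them was detected in the irradiated primary tumour. The largest negative differences were those of miR-698 (-3.43 ± 0.17), miR-346 (-2.90 ± 0.24), miR-2140 (-2.73 ± 0.11), miR-764-5p (-2.52 ± 0.39, dim on both arrays), miR-2134 (-2.21 ± 0.12) and miR-1196 (-2.14 ± 0.12), and miR-1898 was at least 46.2-fold lower, miR-1191 at least 3.45-fold and miR-343 at least 3.11-fold.

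Here 44 of 344 probes were at least 2-fold higher and 38 at least 2-fold lower; scaling to the 75th percentile gave 30 and 144, with the median of all probes at -0.88, and no normalization gave 52 and 15. The lung list had 6 of 9 members at least 2-fold higher (median 1.72 ± 0.12, above 99.995% of random lists), with miR-126-3p at 2.00 ± 0.18 and miR-30b at 1.81 ± 0.18. The metastasis-suppressing list (median 0.93 ± 0.06, percentile 99.3, 5 of 10 higher and miR-31 lower at -1.49 ± 0.14) and the fibroblast and smooth muscle list (median 0.89 ± 0.14, percentile 99.1, 4 of 11 higher by bounds and 2 lower, among them miR-214 at -1.38 ± 0.19) kept their sign under every scaling, as did the lung list. The fibroblast and smooth muscle median was 0.76 with undetected probes at their bounds and 0.13 with scaling to the 75th percentile. Of the miR-200 family 1 member was detected on both arrays, and with the others at their bounds 2 of 5 were at least 2-fold higher and the median was 0.56 (percentile 96.4). Taken from the values of all 5 the median was 1.26 ± 0.19 (percentile 99.5), which was -0.0062 with scaling to the 75th percentile. The other medians, within the middle 95%, were 0.94 ± 0.27 for hepatocytes (0.60 at the bounds), 0.75 ± 0.12 for lymphocytes, 0.45 ± 0.09 for p53 targets (0.17 at the bounds), 0.35 ± 0.11 for the let-7 family, 0.27 ± 0.17 for neural microRNAs (0 at the bounds) and 0.08 ± 0.10 for muscle. Negative medians were -0.07 ± 0.06 for inflammation and NF-kB, -0.08 ± 0.14 for the Sfmbt2 cluster, -0.23 ± 0.11 for miR-17-92, -0.25 ± 0.06 for the RNA fragment probes, -0.33 ± 0.15 for other epithelial (-0.53 at the bounds) and -0.53 ± 0.09 for metastasis-promoting microRNAs. Those for hepatocytes, p53 targets, let-7 and neural microRNAs were negative with scaling to the 75th percentile, and those for inflammation, the Sfmbt2 cluster, miR-17-92, other epithelial and metastasis-promoting microRNAs were positive without normalization. The myeloid miR-223 differed by 2.53 ± 0.28, miR-486 by 1.47 ± 0.12 and miR-210 by -0.53 ± 0.24, the last of which was positive without normalization.

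Across the 374 probes, the site differences of the 2 arms had a Pearson correlation of 0.59 and a Spearman correlation of 0.56. With probes detected on 1 array at their bounds, 28 probes were at least 2-fold higher in metastases in both arms (5.24 expected for independent lists) and 15 at least 2-fold lower (5.08 expected). In the additive limma fit, 0 of 374 probes passed an adjusted p of 0.05 for site (lowest adjusted p 0.12, with 83 probes at an unadjusted p under 0.05 where chance gives 18.7), and 0 passed for radiation (lowest adjusted p 0.293, with 22 at an unadjusted p under 0.05). For radiation, miR-1, miR-133a and miR-133b had unadjusted p of 0.00392, 0.00126 and 0.00177 in the limma fit, each with a Benjamini-Hochberg adjusted p of 0.293, and passed 0.05 after adjustment in 4, 4 and 3 of 12 alternatives. With detection at 2 times the empty spots, miR-133b was left out by the filter and not tested, so that alternative is no failure for it. Across the alternatives the number called ranged from 0 to 42 for site and from 0 to 7 for radiation.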

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

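All tests of explanations in this part were chosen after the results had been seen. The tests of the UG repeat were also narrowed after a first form had been seen: that form used all 8 detected UG probes outside the repeat family, with a median of 1.27, and the later form kept only those not yet singled out. The opposite radiation responses in the 2 sites were not tested, because each group has 1 array.

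For 4 probes the array of the irradiated primary tumour and that of metastases from irradiated mice moved in opposite directions from their sham arrays by at least 2-fold. The response in metastases exceeded that in the primary tumour by 5.11 on the log2 scale for miR-466f, by 4.13 for miR-466j, by 2.57 for miR-574-5p and by 2.57 for miR-1187. The probes for 5S ribosomal RNA, which serve as controls and enter no comparison, were bright on every array, with a mean signal at least 65.4 times the median of the empty spots.

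In the primary tumour, the fall of the 4 probes belongs to a wider pattern, in which probes whose targets hold UG repeats were brighter on the sham primary tumour array than on the other 3. The rise of the 4 probes in metastases does not involve that array, so the pattern does not cover it. Of 17 detected probes of the miR-297, miR-466, miR-467 and miR-669 family with the motif UGUGUG, 9 were at least 2-fold brighter there than the mean of the other arrays, and of 9 detected family probes with a CA repeat (ACACAC) 3 were, with a median of 0.88, against 0.072 for 5 CA probes outside the family. Outside the family 4 of 5 bright UG probes (miR-206, miR-574-5p, miR-672 and miR-1187, but not let-7b) were at least 2-fold brighter, but these 4 had been singled out before and so test neither explanation, and hybridisation of family transcripts to them was not tested. Hybridisation that follows the UG repeat stays open, since the 3 UG probes outside the family that had not been singled out before had a median of 0.49. Transcription of the repeat family stays open too, because its 12 detected members with neither repeat had a median of -0.01 but none (0) of them rose above 2 times the empty spots on any array, and a biological difference of the sham primary tumour was not tested.

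miR-1, miR-133a and miR-133b were higher on both irradiated arrays. The choices of scaling and background correction tried cannot account for it alone, because the lowest of their 6 differences over all settings was 1.63 on the log2 scale. A trend of the background across the chip was not corrected in any of them. Muscle RNA in the samples of the 10 Gy groups may be a source. Of the 4 other members of the muscle list only 1, miR-206, was detected, and 0 were at least 2-fold higher on both irradiated arrays. In metastases after 10 Gy miR-206 was higher by 3.73. In the primary tumour it already stood at 12.68 on the sham array, so this test cannot decide. miR-206 carries a UG repeat and was bright on the sham primary tumour array without miR-1, which would hide a small share of muscle. A response to radiation stays open as well. Per the labels the primary tumour was the site treated, so a response in metastases need not be the same as that in the primary tumour. In the additive limma fit each of the 3 had a Benjamini-Hochberg adjusted p of 0.293 for radiation, a term that pools the 2 sites. That p takes in no spread between animals, and the tissue taken with each tumour is not known.

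The list of lung microRNAs was higher in metastases in both arms. Scaling cannot account for the lung list, whose median was at least 1.34 under every setting. The high background of the irradiated primary tumour array cannot account for the sham arm. There the median was 1.94 between the 2 sham arrays, whose empty spots differ by a ratio of 1.03. For the 10 Gy arm, which holds the array with the high background, that comparison is no test. RNA of lung or similar organ tissue in the metastasis samples stays open and was not tested, since the list is itself what was seen to differ. Of the 11 lung list members, 5 are also in another list and 6 were detected in the sham primary tumour, and of the 6 members in no other list the 5 detected without radiation and the 4 detected after 10 Gy had medians of 1.97 and 1.77, with undetected probes at their bounds. A difference between the tumour cells at the 2 sites stays open and was not tested, and the labels do not name the organ.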

How the results depend on the processing

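With 1 array per group no replicate was left out, and leaving out an array leaves the additive fit no residual degree of freedom, so the values in the 2 arms stand in its place. A slide as a block was not run, since the files show no slide. Detection at 2 times the empty spots and probes at their bounds were added after seeing the data. Dim probes are 1 limit: on the irradiated primary tumour array the empty spots were at 416.9, and 95 of 700 probes exceeded 2 times that level, against 173 on the sham primary tumour array. Where no cause is given, the cause was not tested.

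The number of probes at least 2-fold apart was 103 for the primary tumour after 10 Gy, 23 for metastases after 10 Gy, 107 between sites without radiation, 82 between sites after 10 Gy and 89 for the difference of responses. With scaling to the 75th percentile these became 215 (primary tumour after 10 Gy), 54 (metastases after 10 Gy), 174 (sites after 10 Gy) and 155 (difference of responses). For metastases after 10 Gy the count became 78 without normalization and 15 with only probes detected on all 4 arrays. With detection at 2 times the empty spots the difference of responses had 56. With probes detected on 1 of 2 arrays at their bounds the counts were 94, 23, 106, 73 and 80. By construction, a threshold of 1.5-fold gave, in the order above, 162, 61, 179, 161 and 164, and one of 4-fold gave 24, 8, 40, 26 and 24.

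The additive limma fit called 0 probes for site and 0 for radiation. Site calls became 42 and radiation calls 7 with scaling to the 75th percentile, 35 and 5 with detection at 2 times the empty spots, 27 and 4 with probes detected on all 4 arrays, and 29 and 3 with the authors' value table. Site calls were 5 without the repeat-cluster and RNA fragment probes and 4 without radiation as a term. In the first 3 of these settings limma estimated infinite prior degrees of freedom, against 1.519 as reported, and the cause of the calls was not tested.

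miR-21 in the primary tumour after 10 Gy (0.48) became 0.57 with cyclic loess, 1.33 with the 75th percentile, -0.088 without normalization and 0.53 with the median of spots. In metastases after 10 Gy (-0.17) it became 0.084, 0.21 and -0.59 with the first 3 of these. Between sites without radiation (0.72) it became 0.063, -0.12 and 0.21, and 0.57 without the repeat-cluster probes. Between sites after 10 Gy (0.07) it became -0.42, -1.24 and -0.28. The passenger strand miR-21*, not detected on the irradiated arrays, can be compared only between sites without radiation, where it became -0.80 with scaling to the 75th percentile. The values 1.06 (primary tumour after 10 Gy), 0.64 (metastases after 10 Gy) and -1.23 (sites after 10 Gy) under that scaling involve an array on which it was not above background and are no measured differences. The median of the miR-200 family between sites after 10 Gy reversed, from 1.26 to -0.0062, with scaling to the 75th percentile. Over list medians, 368 values under alternatives stayed within 1 SD between spots and 199 moved further without a called median changing sign. For single microRNAs 225 stayed and 214 moved. Of the counts 67 stayed within 1.5 times and 27 moved further.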

Other observations

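The tests and the probes singled out in this part were chosen after the values had been seen. Of the 28 probes at least 2-fold higher in metastases in both arms, miR-451 (2.95 without radiation and 3.26 after 10 Gy) and miR-486 (1.42 and 1.47) are made in erythroid cells, and miR-146a (2.49 and 1.92) and miR-146b (1.74 and 1.22) are induced by NF-kB. The lists they belong to did not stand out: without radiation the erythroid list was at percentile 96.7 of random lists and the inflammation and NF-kB list at 80.6, and after 10 Gy the latter had a median of -0.07, positive without normalization. miR-10a and miR-195 were higher by 2.16 and 2.86 without radiation, and after 10 Gy miR-195 was higher by 2.13 and miR-10a at least 3.85-fold higher. The 15 probes lower in both arms included miR-1898, miR-2140 (-3.31 and -2.73), miR-346 (-2.36 and -2.90), miR-2141 (-2.20 and -2.14) and miR-671-5p (-1.23 and -1.73). Also among them were miR-2134, miR-2135, miR-2143, miR-2145 and miR-2146. Like miR-2140 and miR-2141, these matched no gene in the RefSeq table and were not in the RNA fragment list. Whether such probes measure microRNAs was not tested.

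The 7 probes at least 2-fold lower on both irradiated arrays were miR-98, miR-292-5p (-2.53 in the primary tumour and -1.15 in metastases), miR-671-5p (-1.31 and -1.81), miR-714 (-1.45 and -1.56), miR-874 (-2.51 and -2.26), miR-1940 (-1.78 and -1.10) and miR-1956 (-2.79 and -1.49). Of these, miR-714 is on the list of RNA fragment and GC-rich probes. miR-98 was not detected in the irradiated primary tumour, where it was at least 2.33-fold lower than in the sham one, and differed by -2.04 in metastases. With scaling to the 75th percentile, miR-98 and miR-1940 were under 2-fold lower in the primary tumour, at -0.84 and -0.70, so that the bound of miR-98 does not hold under that scaling. The let-7 members differed by -0.39 to 0.86 in the primary tumour and by -0.22 to 0.15 in metastases, all under 2-fold, and in the primary tumour 7 of these 8 changed sign under another scaling, while let-7a was at 0.

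miR-122 and miR-205 were not detected in either primary tumour. On the array of metastases from irradiated mice they stood at 716.5 and 173.6 intensity units above the empty spots, against 53.79 and 32.99 in sham metastases. miR-200c stood at 54.34 units above the empty spots in the sham primary tumour and at 3685 in sham metastases. miR-574-5p was brighter on the sham primary tumour array than the mean of the other 3 by 1.75 on the log2 scale, while miR-574-3p, from the other arm of the same precursor, differed by 0.07. With the longer motif UGUGUGU in place of UGUGUG, 7 of 15 detected family probes were at least 2-fold brighter on the sham primary tumour array, and 2 of 14 family probes with neither repeat were, miR-297a and miR-467h, both of which hold the shorter motif.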
